A study of Mus musculus with 16 samples.

How the data were processed

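RNA sequencing libraries from 16 placenta samples of C57BL/6 mice at embryonic day 13 were compared, 4 each from wild-type and Asc-/- pregnancies with PEGIL11 or PEG. Per the labels, mated females received once-daily injections under the skin of 500 µg/kg/day PEGIL11 or of PEG from day 10 to day 12. Placental RNA was taken up with the RNeasy kit and libraries were made with the Ribo-Zero Gold protocol, which removes ribosomal RNA. The labels do not say whether a sample is 1 placenta or a pool, or which samples share a litter. The numbers in the sample names run in separate ranges for the 2 genotypes, and no label says whether the genotypes shared a cohort.

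Of the deposited tables the authors gave a full table in counts, with 40836 gene symbols, of which 10891 had no count in any library, and an mRNA table in counts with 21394 of these symbols, 0 cells of which differed from the full table. The third deposited table holds a normalized signal for 14158 genes. Divided by 1 constant per library, 100% of its values lay within 0.01 of a whole read. For each library, 1 M divided by that constant lay between 0.924 and 1.07 times the library's mRNA total. The signal is thus CPM (counts scaled to a library of 1 M) of a scaled library size and not a log. The submitters' processing notes name bcl2fastq 2.20.0.422, STAR 2.5.3a and edgeR without a version, and the build mm10. The counting program, the annotation, the strand setting and the handling of reads shared between genes are not given in the sources used here. All columns of per-sample values were used.

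All tests used the full count table with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 in R 4.3.3, and figures used Python 3.11.15 with matplotlib 3.10.9. Genes were kept by filterByExpr with the 4 groups (minimum count 10, minimum total count 15), which left 16612. Of these 16455 (99.1%) had a coordinate in the GRCm38.p6 annotation. Scaling used TMM factors, which lay between 0.929 and 1.06. A quasi-likelihood model with 1 mean per group was fitted to all 16 libraries, with 12 residual degrees of freedom and a common dispersion of 0.0497 (a biological coefficient of variation of 22.3%). The 5 comparisons were IL11 against PEG in wild type and in Asc-/-, the difference of these responses, and Asc-/- against wild type under PEG and under IL11. Calls had a Benjamini-Hochberg FDR under 0.05 over all genes of a comparison. Levels are CPM of the TMM-scaled library, and log2 scores per library used an offset of 0.5 CPM.

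Library totals lay between 22.6 and 33.0 M counts (M for mega), with a median of 26.6 M, and 96.9% to 98.0% of them were in the mRNA table. Between libraries of a group the Pearson r of log2 CPM was 0.968 to 0.996 over 24 pairs, and the chi-square per degree of freedom, over genes with at least 20 counts in a pair, was 16.5 to 103, so the spread between samples exceeded counting error. For a group at 0 counts a floor of 3 counts over the group gave a lower bound of the fold. For 1 to 4 counts the ratio is given with an exact 95% interval. The pipeline was tested on simulated data of this size, with 100 genes changed 2-fold and 100 changed 4-fold. At 2-fold it recovered 77% in both IL11 comparisons, 49% for the difference between them, and 85% and 79% for the genotypes under PEG and IL11. At 4-fold it recovered 97% and 98%, 89%, and 95% and 93%. False calls were 2.82% to 6.12% of calls. Each gene was drawn independently around a mean common to the groups, with changes only in genes with a mean CPM of at least 1. Differences of tissue or fetal sex between libraries were not simulated, so these rates may not hold for the real libraries.

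Before the data were examined, 31 gene lists, the test of each comparison, the alternatives and the rule for named genes were fixed. The lists cover IL11/gp130 pathway components, STAT3-responsive genes, the acute-phase response, inflammasome and pyroptosis, inflammatory cytokines and chemokines, the interferon response, trophoblast progenitors, syncytiotrophoblast, trophoblast giant cells, spongiotrophoblast and glycogen cells, decidual stroma, endothelium, pericytes and smooth muscle, extracellular matrix and fibroblasts, uterine natural killer cells, macrophages and monocytes, neutrophils, T cells, B cells and dendritic cells, platelets and megakaryocytes, erythroid cells, visceral endoderm and yolk sac, preeclampsia-associated and angiogenic factors, hypoxia and glycolysis, oxidative phosphorylation, cell cycle, the unfolded protein response, immediate-early and heat-shock genes, cholesterol synthesis, imprinted genes, fetal sex markers, and the Pycard neighbourhood with strain-marker genes. Some genes are in more than 1 list, for example 8 decidual stroma genes. Apart from the sex markers, given as values, each list was tested in each comparison with camera at a preset correlation between genes of 0.01, two-sided, adjusted over the 30 lists. Beside it stand camera with an estimated correlation and fry, which tests whether the genes of a list move, on balance, one way and compares the list with no other genes. Counts of members that passed are given over all genes and adjusted over the list alone.

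Named genes were Pycard, up to 10 higher and 10 lower genes per comparison with the smallest p among those that passed with a mean CPM of at least 1 and a symbol that is not a predicted or clone name, up to 4 members with the smallest p of each list described, and members that passed adjusted over the list alone. Where fewer than 5 genes passed, the 5 with the smallest p were named as values that did not pass. Errors are SE for log2 changes and SD over 4 libraries for levels.

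The alternatives fixed beforehand were RLE size factors, no filter on low counts, a filter at a mean CPM of 1, DESeq2 with default settings, limma voomWithQualityWeights, a fit with only the groups compared, the replicate number as a block, and leaving out each library. Alternatives chosen after seeing the data were the mRNA table, the reads recovered from the normalized table, the mean log2 CPM of the Y-linked genes as a covariate, maternal and yolk sac scores as covariates, and 14 libraries, without wild-type PEG replicate 1 and Asc-/- IL11 replicate 4. The maternal score is the mean log2 CPM of the decidual stroma and natural killer cell lists without genes of a trophoblast list, and the yolk sac score that of the visceral endoderm and yolk sac list. The test foreseen for values without counts was not needed. For each comparison the libraries were also split in other ways: all 35 splits of the 8 libraries compared, and 100 drawn regroupings of treatment within genotype for the difference of the responses. For the latter, 100 arrangements of the residuals of a model with additive genotype and IL11 effects, on log2 CPM with a prior count of 2 and limma with a trend, were added after seeing the data.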

Results

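RNA from mouse placentas collected at embryonic day 13 was sequenced in 16 libraries, 4 in each of 4 groups. Mated wild-type or Asc-/- females had received daily injections under the skin of PEGIL11, which is interleukin 11 (IL11) joined to polyethylene glycol (PEG), at 500 µg/kg/day on days 10 to 12, or PEG alone. Asc-/- mice carry a null allele of Pycard, the gene of the adaptor ASC, which links inflammasome sensors to caspase-1. The libraries held between 22.6 and 33.0 M counts (M for mega). The group means were 24.7 ± 1.62 M in wild type with PEG (SD, n = 4) and 24.9 ± 2.60 M in wild type with IL11. They were 28.4 ± 3.14 M in Asc-/- with PEG and 27.5 ± 2.63 M in Asc-/- with IL11. The Asc-/- libraries were deeper than the wild-type libraries (28.0 ± 2.72 against 24.8 ± 2.01 M, n = 8 each, exact two-sided permutation p = 0.0148). The labels do not say whether the 4 samples of a group came from separate litters or animals, so p-values measure only the spread between these samples.

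Pycard (chromosome 7, 127991373 to 127993867, GRCm38.p6) followed the genotype labels in all 16 libraries. Under PEG it had 110 counts in the wild-type group, 1.13 ± 0.0801 CPM (counts scaled to a library of 1 M, SD, n = 4), and 0 counts in the Asc-/- group. A floor of 3 counts over the Asc-/- group put it at least 43.7-fold lower. Under IL11 it had 145 counts in wild type and 1 count in Asc-/-, a ratio of 158 with a 95% exact counting interval of 28.0 to 6294. Without Asc-/- with IL11 replicate 2, the library with that count, it was at least 37.4-fold lower by the floor. Floors and intervals cover counting error only.

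The libraries differed within groups in the tissues and the fetal sex that they represented. Y-linked transcripts (Ddx3y, Eif2s3y, Kdm5d and Uty) were at 20.7 CPM or more each in 7 libraries, here called high, and at 0.230 CPM or less each in the other 9. The 7 were wild type with PEG replicate 1, all 4 of wild type with IL11, Asc-/- with PEG replicate 3 and Asc-/- with IL11 replicate 2. Xist, the non-coding RNA of the inactive X chromosome, lay between 6.47 and 134 CPM in these 7 and between 1103 and 1392 CPM in the other 9. Afp, the alpha-fetoprotein gene of visceral endoderm, chosen after its values were seen, ranged from 18.8 to 12257 CPM within Asc-/- with IL11 and from 19.7 to 5950 CPM within wild type with PEG. It lay between 7496 and 16336 CPM in wild type with IL11. A maternal score, the mean log2 CPM of decidual stroma and uterine natural killer cell markers, was 4.05 to 4.10 in wild type with PEG and 2.92 to 3.45 in wild type with IL11. In Asc-/- it was 4.78 to 5.48 with PEG and 4.30 to 5.61 with IL11. The first principal component held 42.5% of the variance and the second 20.5%. On the first component, wild type with PEG replicate 1 and Asc-/- with IL11 replicate 4 lay apart from the other 3 libraries of their groups.

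**Figure D1:**
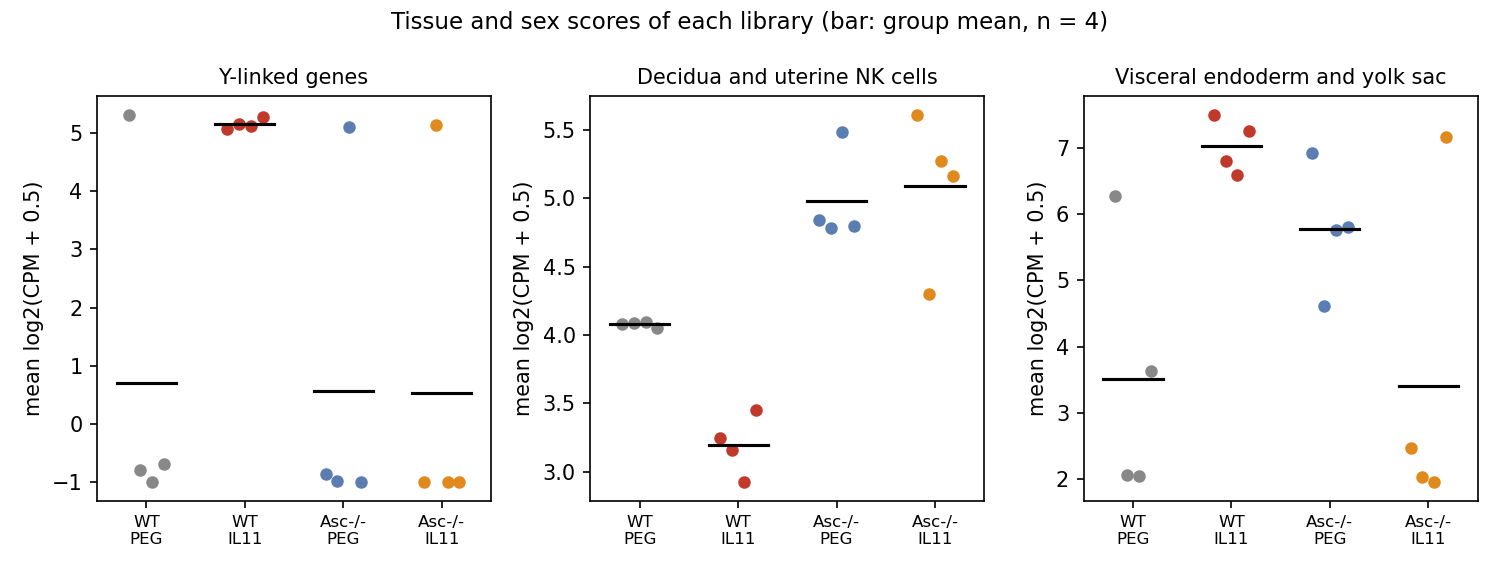
Tissue and sex scores of the 16 libraries, as mean log2(CPM + 0.5) of the genes named over each panel, with libraries as points and group means as bars. The 4 wild-type IL11 libraries all have high Y-linked transcripts, have yolk sac scores of 6.58 to 7.50 and have maternal scores of 2.92 to 3.45.

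The first comparison concerned the response of the wild-type placenta to IL11. Clec12a, which encodes an inhibitory lectin receptor of myeloid cells, rose from 11.1 ± 2.14 to 54.4 ± 14.6 CPM (SD, n = 4 each), a log2 change of 2.29 ± 0.29 (SE, adjusted p = 0.00336). Lgmn, the lysosomal protease legumain, rose from 390 ± 13.3 to 756 ± 171 CPM (0.96 ± 0.13, adjusted p = 0.00352). The placental cathepsin genes on chromosome 13 moved both ways. Cts8 rose from 1.18 ± 1.07 to 33.0 ± 26.6 CPM (log2 4.81 ± 0.73), Cts7 rose by 4.49 ± 0.98 and the abundant Ctsj by 0.82 ± 0.18. Ctsm fell from 1842 ± 306 to 730 ± 135 CPM (-1.34 ± 0.15) and Cts3 from 3494 ± 643 to 1231 ± 457 CPM (-1.50 ± 0.24). Prolactin-family genes of the same chromosome also moved both ways. The decidual member Prl8a2 fell, as given with the decidua, and Prl6a1 rose from 63.5 ± 9.77 to 217 ± 62.3 CPM (log2 1.78 ± 0.26). Prl4a1 rose by 1.99 ± 0.32, Prl5a1 by 2.36 ± 0.40, Prl7b1 by 1.82 ± 0.34 and Prl7d1 by 1.17 ± 0.20. Cathepsin and prolactin genes have close paralogs, and how reads shared between paralogs were counted is not given in the sources used here, so the split within each family is uncertain.

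Of 16612 genes tested with edgeR's quasi-likelihood test, 408 rose and 746 fell at an FDR under 0.05 in wild type. In the giant cell list 8 of 24 tested genes rose and 3 fell (8 and 4 adjusted over the list alone), without a shift of the list (camera adjusted p = 0.146). In the spongiotrophoblast and glycogen cell list 5 of 41 rose and 11 fell (5 and 19 adjusted over the list alone; median -0.45, camera adjusted p = 0.00211; adjusted p = 0.547 with an estimated correlation). The falling members included the pregnancy-specific glycoprotein gene Psg17 (-1.25 ± 0.22) and Ceacam12 (-1.30 ± 0.22). In the syncytiotrophoblast list Ly6e, the receptor of syncytin A, fell by 0.62 on the log2 scale, Syna, which encodes that syncytin, fell by 0.44, and the amino acid transporter gene Slc7a8 rose by 0.44. In all, 1 member of 26 rose and 4 fell (1 and 6 adjusted over the list alone; camera adjusted p = 0.00211; adjusted p = 0.433 with an estimated correlation). Among trophoblast progenitor genes Esrrb rose (1.22 ± 0.22), and Eomes (-0.92 ± 0.26) and Ly6a (-2.05 ± 0.34) fell. These were 1 and 2 of 19 tested (2 and 3 adjusted over the list alone, camera adjusted p = 0.645). The matrix genes Timp3 (1.20 ± 0.20), Timp1 (0.97 ± 0.21) and Mmp9 (2.02 ± 0.39), which encode inhibitors of metalloproteinases and a gelatinase, rose. In their list 4 of 39 members rose and 1 fell (5 and 1 adjusted over the list alone, camera adjusted p = 0.0762). Outside the lists Crispld2 (1.69 ± 0.26), the kinase gene Hunk (1.10 ± 0.16) and the semaphorin gene Sema5b (1.5 ± 0.23) rose. So did Actr3b (1.05 ± 0.15), Aplp1 (0.90 ± 0.13) and Ttc7 (0.87 ± 0.14). Among those that fell were Ptgdr2, a prostaglandin D2 receptor (-1.80 ± 0.21), Pdk4, a kinase that inhibits pyruvate dehydrogenase (-1.42 ± 0.18), and the intermediate filament gene Synm (-1.69 ± 0.23). The peptide receptor gene Adcyap1r1 (-1.92 ± 0.26), the bicarbonate transporter gene Slc4a5 (-1.72 ± 0.22), Fndc4 (-0.68 ± 0.09) and Xxylt1 (-0.58 ± 0.07) fell too.

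**Figure D2:**
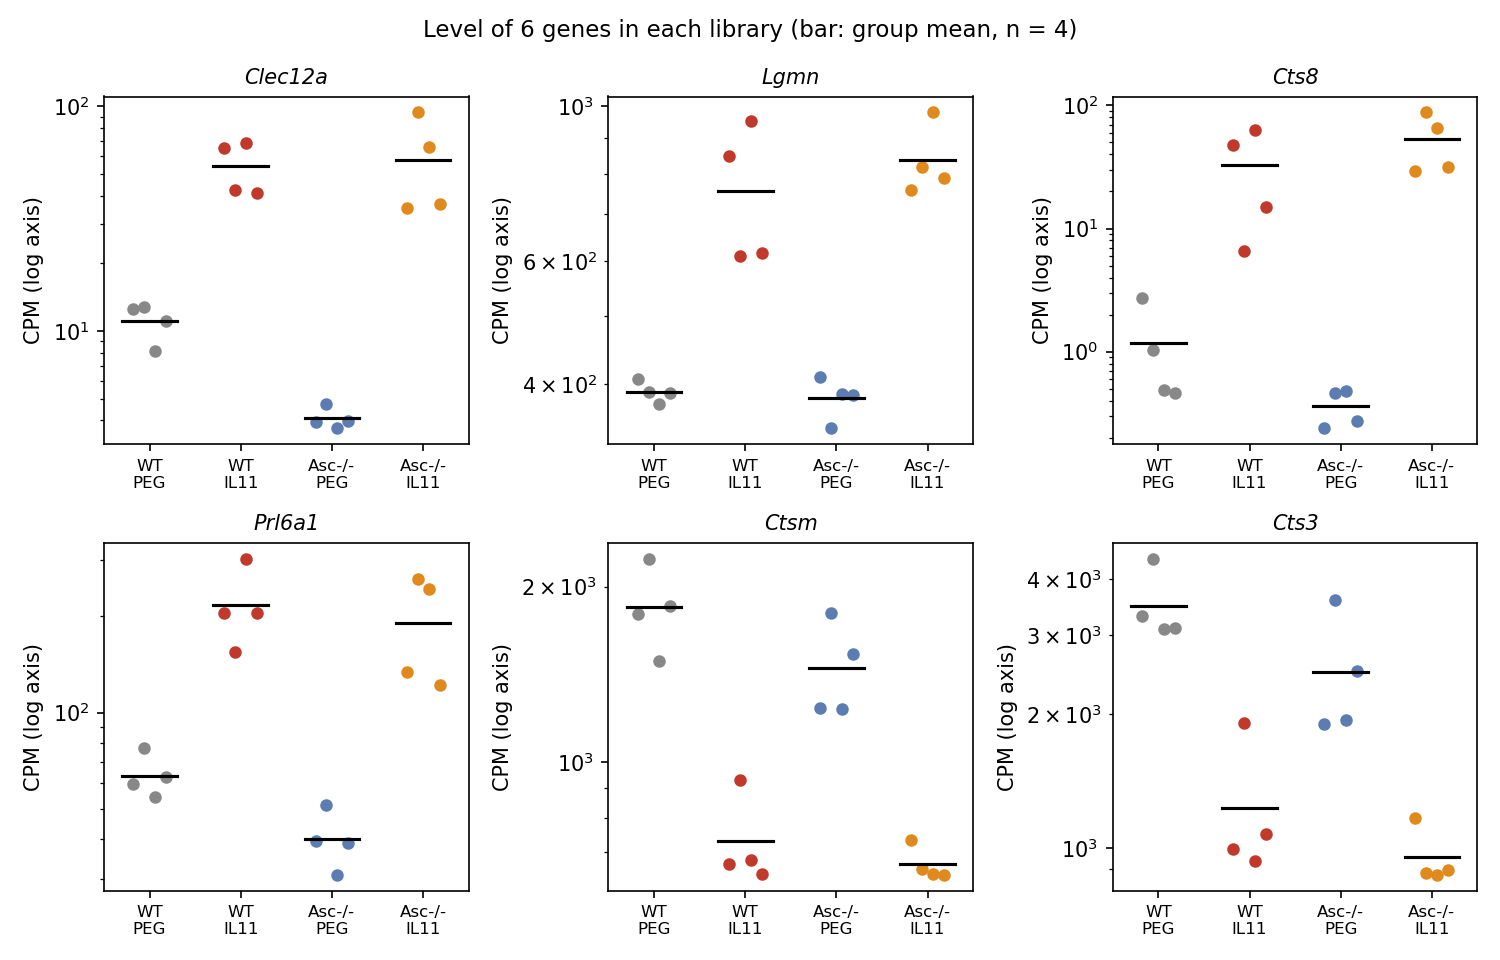
Levels of 6 genes in each library (CPM, log axis), by group, with libraries as points and group means as bars. Clec12a, Lgmn, Cts8 and Prl6a1 are higher and Ctsm and Cts3 lower after IL11 in both genotypes.

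Transcripts of maternal decidua and of uterine natural killer cells were lower after IL11 in wild type. Of 30 decidual stroma genes 14 fell and 1 rose (17 and 3 adjusted over the list alone), with a median log2 change of -0.89. The decidual prolactin gene Prl8a2 fell from 460 ± 212 to 112 ± 8.75 CPM (-2.03 ± 0.32). The progesterone receptor gene Pgr fell from 9.78 ± 1.91 to 1.90 ± 0.948 CPM (-2.36 ± 0.43), and the genes Hoxa10 (-1.89 ± 0.34) and Des (-2.11 ± 0.36) fell as well. The member that rose, Prl6a1, also belongs to the spongiotrophoblast list. Of 19 natural killer cell genes 7 fell (14 down and 1 up adjusted over the list alone), with a median of -1.80. Among them were Srgn, the granule proteoglycan gene (250 ± 64.8 to 74.8 ± 17.6 CPM, -1.74 ± 0.37), and the granzyme gene Gzmc (54.6 ± 25.1 to 12.7 ± 8.94 CPM, -2.10 ± 0.54). Both lists passed camera (adjusted p = 6.96e-10 and 7.42e-10; adjusted p = 0.433 for each with an estimated correlation). Beside these lists, Y-linked transcripts were high in 1 PEG library and all 4 IL11 libraries. The visceral endoderm and yolk sac list had a median of 2.58, and 5.40 with 10 genes up without PEG replicate 1 (camera adjusted p = 6.42e-10; adjusted p = 0.433 with an estimated correlation). With all libraries 0 of its 28 members passed by edgeR with either adjustment, 11 had an unadjusted p under 0.05, and DESeq2 called 3 and limma with library quality weights 26. Tfpi2, an imprinted gene of a serine protease inhibitor, fell from 186 ± 87.8 to 23.4 ± 7.48 CPM (-2.99 ± 0.39), and the matrix gene Emilin2 by 2.71 on the log2 scale. Of preeclampsia-associated genes Inhba, an activin subunit (-2.43 ± 0.38), Pappa (-2.15 ± 0.39), the vasodilator peptide gene Adm (-1.53 ± 0.34) and the VEGF receptor gene Kdr (-0.44 ± 0.11) fell. That was 4 of 32 (1 up and 4 down adjusted over the list alone; camera adjusted p = 0.00858; adjusted p = 0.433 with an estimated correlation).

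In the interferon list 7 of 39 genes fell in wild type (11 down and 1 up adjusted over the list alone), among them the antiviral gene Rsad2 (-0.84 ± 0.14) and the class I antigen gene H2-K1 (-1.28 ± 0.29). In the unfolded protein response list 6 of 30 fell (17 adjusted over the list alone), including the chaperone gene Hspa5 (-0.47 ± 0.13) and Chac1 (-2.31 ± 0.52). Endothelial genes fell in 3 of 20 (10 adjusted over the list alone), Pecam1 by 0.46 on the log2 scale. Oxidative phosphorylation genes rose in 4 of 44 (15 adjusted over the list alone), such as Sdhd (0.33 ± 0.08) and Atp5o (0.38 ± 0.10). Cell cycle genes rose in 3 of 40 (10 adjusted over the list alone), Mcm7, Mcm3 and Birc5. Cholesterol synthesis genes rose in 2 of 24, Hmgcs1 (0.74 ± 0.20) and Lss (0.65 ± 0.17), with 13 up and 1 down adjusted over the list alone. The camera adjusted p lay between 1.03e-08 and 2.63e-05 for these 6 lists, and the adjusted p was 0.433 with an estimated correlation for 5 of them and 0.502 for the cell cycle list. Of acute-phase genes Saa3 (4.05 ± 0.80) and Steap4 (3.28 ± 0.81) rose, 2 of 21 by either adjustment (camera adjusted p = 0.0332, and adjusted p = 0.547 with an estimated correlation). The acute-phase list shares genes with the yolk sac list, and a part played by yolk sac RNA was not tested. Of the inflammasome list 1 of 28 genes fell, the regulator Nlrc5 (-1.38 ± 0.37), and 0 when adjusted over the list alone (camera adjusted p = 0.275). Of STAT3-responsive genes Timp1 and Birc5 rose, 2 of 20 (3 up and 2 down adjusted over the list alone, camera adjusted p = 0.394). Clcf1, a cytokine of the gp130 family, fell (-1.03 ± 0.27), the 1 of 13 pathway components that passed (2 adjusted over the list alone; camera adjusted p = 0.0114; adjusted p = 0.433 with an estimated correlation). The number of genes called in wild type was 70 with the Y-linked score as a covariate, and 1, which rose, with the maternal and yolk sac scores as covariates, which also turned the sign for H2-K1 and Adm. Maternal scores of wild type with PEG and with IL11 did not overlap, so that covariate could hardly be told from IL11. The number called was 2121 with DESeq2, 4234 with limma and library quality weights, and 2343 without wild type with PEG replicate 1 and Asc-/- with IL11 replicate 4. More genes fell than rose with all libraries by edgeR, but 2292 rose and 1942 fell with limma, and 1306 rose and 1037 fell without these 2 libraries. Leaving out 1 library gave 1773, 552 and 718 genes without PEG replicates 1, 3 and 4, and 467, 2269, 344 and 574 genes without IL11 replicates 1, 2, 3 and 4.

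The second comparison concerned the response of the Asc-/- placenta to IL11. Clec12a rose from 4.08 ± 0.452 to 57.9 ± 27.9 CPM (SD, n = 4 each; log2 3.83 ± 0.31, adjusted p = 2.76e-05). Lgmn rose from 382 ± 26.6 to 836 ± 98.7 CPM (1.13 ± 0.13), and Prl6a1 from 40.2 ± 8.29 to 190 ± 72.5 CPM (2.25 ± 0.26). Cts8 rose from 0.361 ± 0.124 to 53.8 ± 28.3 CPM (7.22 ± 0.84) and Cts7 by 8.18 ± 1.20, and Ctsj, a far more abundant cathepsin gene, rose by 1.14 ± 0.18. Ctsm fell from 1451 ± 273 to 667 ± 44.7 CPM (-1.12 ± 0.15) and Cts3 by 1.38 on the log2 scale. Prl4a1 (2.53 ± 0.33), Prl7b1 (2.88 ± 0.35) and Prl2a1 (1.40 ± 0.16) rose. Ceacam1, a cell adhesion gene, rose from 23.5 ± 1.15 to 66.2 ± 6.09 CPM (1.5 ± 0.12, adjusted p = 2.76e-05). Cyp17a1, a steroid hydroxylase gene (1.83 ± 0.21), Pros1, which encodes the anticoagulant protein S (0.88 ± 0.10), Timp3 (2.07 ± 0.20) and the matrix gene Matn1 (4.28 ± 0.44) rose too. Genes that fell included the purine receptor gene P2ry1 (-2.10 ± 0.31), Ptgdr2 (-1.43 ± 0.21) and Synm (-1.52 ± 0.23). Others were Creb3l1 (-1.73 ± 0.28), Ism1 (-2.27 ± 0.37), the potassium channel gene Kcnk1 (-0.99 ± 0.14), Mexis (-1.12 ± 0.17) and Cdca7l (-0.81 ± 0.12).

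By edgeR 307 genes rose and 169 fell in Asc-/-. In the giant cell list 7 of 24 rose and 2 fell (10 and 2 adjusted over the list alone; median 0.33, camera adjusted p = 2.07e-06; adjusted p = 0.234 with an estimated correlation). In the spongiotrophoblast list 6 of 41 rose and 2 fell, Psg17 and Ceacam12 (7 and 3 adjusted over the list alone, camera adjusted p = 0.181). The list's median of -0.16 differed in sign from its mean of 0.16. Neutrophil genes shifted upward as a list, with a median of 1.07, a camera adjusted p of 3.78e-10 and an adjusted p of 0.0239 with an estimated correlation. Of 12 tested, Chil3, a chitinase-like gene (2.36 ± 0.36), Mmp9 (2.43 ± 0.39) and the chemokine receptor gene Cxcr2 (0.35 ± 0.09) rose, and 10 rose adjusted over the list alone. The cells that made these transcripts were not tested. STAT3-responsive genes rose in 3 of 20 and fell in 1 (5 and 2 adjusted over the list alone; camera adjusted p = 0.00274; adjusted p = 0.234 with an estimated correlation). They were Socs3, the feedback inhibitor of gp130 signalling (22.4 ± 2.03 to 87.3 ± 43.3 CPM, 1.96 ± 0.32, adjusted p = 0.00454), and Bcl3 (11.3 ± 2.09 to 45.7 ± 16.5 CPM, 2.01 ± 0.35). Timp1 also rose (1.27 ± 0.21) and Fgl1 fell (-1.02 ± 0.25). Stat3 itself rose by 0.36 ± 0.08, the 1 of 13 pathway components that passed by either adjustment (camera adjusted p = 0.537). In wild type Socs3 did not pass over all genes, but lay between 18.0 and 25.3 CPM with PEG. With IL11 it was 46.0, 22.0, 58.3 and 35.4 CPM in replicates 1 to 4. By edgeR 0 genes passed for the difference of the responses, so the Socs3 call is not shown to be particular to Asc-/-.

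Acute-phase genes rose in 3 of 21 in Asc-/- by either adjustment, without a shift of the list (camera adjusted p = 0.120, median -0.01, mean 0.33). They were the serpin genes Serpina3n (11.4 ± 3.21 to 104 ± 58.1 CPM, 3.19 ± 0.43) and Serpina3m (3.10 ± 0.59), and Hp, the haptoglobin gene (1.30 ± 0.32). The 2 serpins are close paralogs in 1 cluster, so their split is uncertain. In the list of T cells, B cells and dendritic cells the dendritic cell gene Clec9a rose (1.53 ± 0.27). Flt3 (-1.02 ± 0.16), the class II antigen gene H2-Aa (-1.86 ± 0.45) and Ighm (-0.93 ± 0.23) fell. Of 13 tested, 1 rose and 3 fell (1 up and 8 down adjusted over the list alone; camera adjusted p = 0.000365; adjusted p = 0.234 with an estimated correlation). Of the inflammasome list Il1r1, the interleukin 1 receptor gene, rose (0.95 ± 0.19), 1 of 28 by either adjustment (camera adjusted p = 0.762). Of the interferon list Irf1 rose (0.55 ± 0.14), and Rsad2 (-0.61 ± 0.14) and Cmpk2 (-0.62 ± 0.15) fell. These were the calls among 39 tested by either adjustment (camera adjusted p = 0.0220; adjusted p = 0.798 with an estimated correlation). Of natural killer cell genes the integrin gene Itga2 (1.29 ± 0.19) and the cytokine receptor gene Il2rb (0.73 ± 0.17) rose, 2 of 19 (3 adjusted over the list alone, camera adjusted p = 0.0694). Decidual stroma genes had 1 of 30 up, Prl6a1, and 0 down by either adjustment (median 0.19, camera adjusted p = 0.0280; adjusted p = 0.798 with an estimated correlation). Of cholesterol synthesis genes the squalene epoxidase gene Sqle fell (-0.24 ± 0.06), 1 of 24 (3 down adjusted over the list alone; median -0.20, but 0.022 with the maternal and yolk sac scores; camera adjusted p = 0.000580; adjusted p = 0.798 with an estimated correlation). Among progenitor genes Esrrb rose (1.33 ± 0.22) and Epcam fell (-0.40 ± 0.09), of 19 (2 up and 1 down adjusted over the list alone, camera adjusted p = 0.539). With 1 library left out the decidual median lay between 0.03 and 0.37, the cholesterol synthesis median between -0.39 and -0.08, and the spongiotrophoblast median between -0.25 and 0.01. The yolk sac list had a median of -0.53, with 0 of 28 genes past the threshold by edgeR, 0 at an unadjusted p under 0.05, 0 by DESeq2 and 10 by limma with library quality weights. Its camera adjusted p was 0.000342 (adjusted p = 0.798 with an estimated correlation). The median depended on single libraries: it was 0.09 and -0.84 without PEG replicates 1 and 2, between -0.21 and -0.20 without IL11 replicate 1, 2 or 3, and -4.79 with 20 genes down without IL11 replicate 4. Y-linked transcripts were high in 1 library of each group. The number of genes called in Asc-/- was 851 with DESeq2, 1167 with limma and library quality weights, and 1201 without wild type with PEG replicate 1 and Asc-/- with IL11 replicate 4. Leaving out 1 library gave 266, 283, 293 and 260 genes without PEG replicates 1, 2, 3 and 4, and 306, 184 and 821 without IL11 replicates 2, 3 and 4. More genes rose than fell with all libraries, but 389 rose and 432 fell without IL11 replicate 4, and 474 rose and 727 fell without that library and wild type with PEG replicate 1.

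The 2 responses shared genes beyond the overlap of independent lists. In the same direction 125 genes rose in both genotypes, where independent lists would share 7.54, and 84 fell in both, against 7.59. By edgeR 0 genes passed in opposite directions, where independent lists would share 4.15 and 13.8. At an unadjusted p under 0.05 the wild-type comparison held 4451 genes and the Asc-/- comparison 2489, and DESeq2 called 5 genes in opposite directions and limma with quality weights 60. The shared genes that rose included Clec12a, Lgmn, Prl6a1, Cts8 and Timp3, and those that fell Ctsm, Cts3, Ptgdr2 and Synm. Across the 16612 genes, which are not independent replicates, the log2 changes of the genotypes had a Pearson r of 0.116 and a Spearman rho of 0.228. Among the 476 genes called in Asc-/- the r was 0.909 and 96.0% had the same sign, and among the 1154 called in wild type the r was 0.516. The number shared was 29 with the Y-linked score as a covariate (8 up and 21 down), 0 with the maternal and yolk sac scores, 407 with DESeq2, 558 with limma and library quality weights, and 122 when each genotype was fitted alone. With the maternal and yolk sac scores the 209 genes kept their sign in wild type, with a median log2 change signed by direction of 0.64 against 0.82 without and a median SE of 0.27 against 0.17. The number shared was 115, 102, 341 and 93 (44 up and 49 down) without wild-type PEG replicate 3 and wild-type IL11 replicates 1, 2 and 3, and 129 and 113 without Asc-/- PEG replicate 4 and Asc-/- IL11 replicate 3. In opposite directions 82 and 5 genes passed without Asc-/- IL11 replicates 4 and 2. Without both wild-type PEG replicate 1 and Asc-/- IL11 replicate 4, 382 genes passed in opposite directions and 266 in the same, and the r across all genes was -0.528. Without these 2 libraries yolk sac scores did not overlap between PEG and IL11 in either genotype and differed in opposite directions. They were 2.05 to 3.63 with PEG and 6.58 to 7.50 with IL11 in wild type. In Asc-/- they were 4.62 to 6.92 with PEG and 1.95 to 2.47 with IL11. Y-linked transcripts were high in no wild-type PEG library left and in all wild-type IL11 libraries. That r cannot tell opposed responses to IL11 from tissue or fetal sex. The r across the 16612 genes was 0.00373 and 0.0506 without wild-type PEG replicate 1 and wild-type IL11 replicate 3. It was 0.321, 0.0357 and 0.050 without Asc-/- PEG replicates 1, 2 and 3, and 0.271, 0.217 and -0.347 without Asc-/- IL11 replicates 1, 3 and 4.

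**Figure D3:**
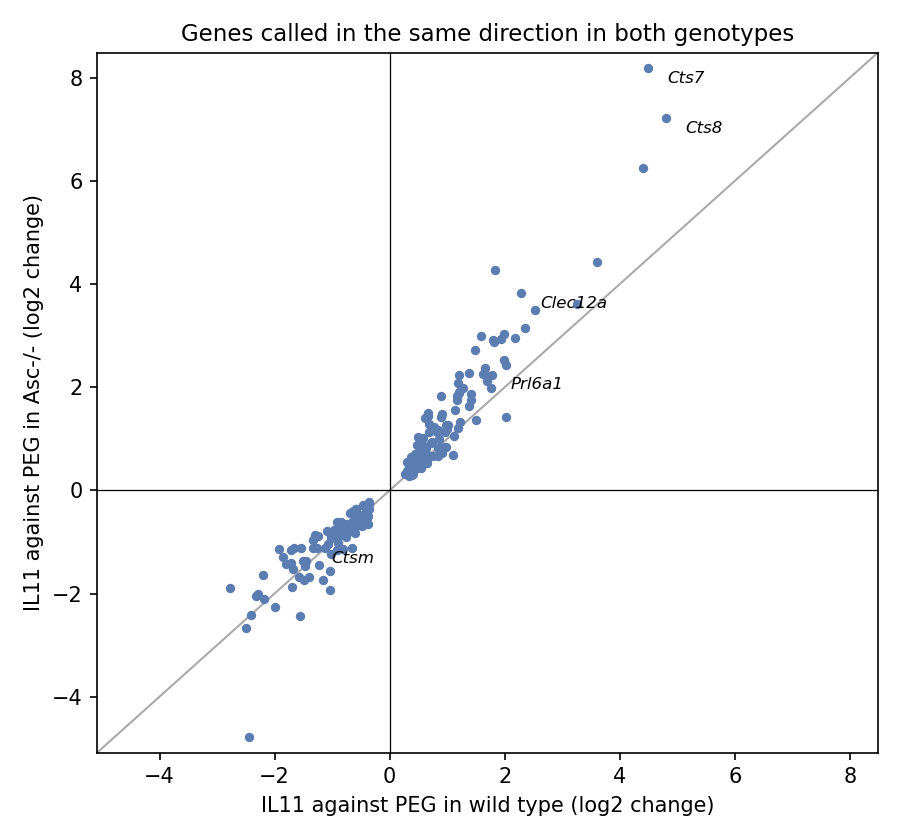
Log2 change after IL11 in wild type (horizontal) and in Asc-/- (vertical) of the 209 genes called in the same direction in both genotypes. Each point is a gene, the line marks equal changes, and 125 genes lie at the upper right and 84 at the lower left.

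The difference of the IL11 response between genotypes was tested directly as an interaction. By edgeR 0 genes passed, with 1919 at an unadjusted p under 0.05 and a smallest adjusted p of 0.101. DESeq2 called 210, and limma with library quality weights 1410. The 5 smallest p-values belonged to genes that were lower after IL11 in wild type and not in Asc-/-, each with an adjusted p of 0.101. Shisa3, a Wnt and FGF signalling modulator, had 16 ± 4.85 and 2.22 ± 1.15 CPM in wild type with PEG and IL11 and 35.9 ± 15.9 and 47.9 ± 20.1 CPM in Asc-/- (difference 3.28 ± 0.55). The growth factor gene Fgf2 had 11.0 ± 2.67 and 3.22 ± 0.853 CPM in wild type and 18.0 ± 6.16 and 28.3 ± 10.1 CPM in Asc-/- (2.43 ± 0.43). Lmcd1 had 34.1 ± 8.02 and 11.5 ± 2.97 CPM in wild type and 74.2 ± 23.0 and 132 ± 52.2 CPM in Asc-/- (2.40 ± 0.42). The muscle gene Myoz2 had 0.742 ± 0.260 and 0.116 ± 0.0800 CPM in wild type and 1.23 ± 0.198 and 1.70 ± 0.511 CPM in Asc-/- (3.14 ± 0.55). The predicted gene Gm30224 had 6.81 ± 1.71 and 1.34 ± 0.419 CPM in wild type and 15.6 ± 4.35 and 23.1 ± 10.1 CPM in Asc-/- (2.91 ± 0.48). Asc-/- PEG replicate 3, with the highest maternal score of its group (5.48), had its highest Shisa3, Fgf2, Lmcd1 and Gm30224 but its lowest Myoz2. Asc-/- IL11 replicate 2, with the lowest maternal score of its group (4.30), had its lowest level of all 5. Whether these genes differed through the share of maternal tissue was not tested.

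Several lists differed between the 2 responses by camera with its preset correlation, and none of the 30 with an estimated one (smallest adjusted p = 0.123). The decidual stroma list had a median difference of 1.38 (camera adjusted p = 1.82e-17; adjusted p = 0.123 with an estimated correlation). It had 18 up and 1 down adjusted over the list alone, among them Prl8a2 (2.53 ± 0.45) and Pgr (2.72 ± 0.58). The natural killer cell list had a median of 1.94 (camera adjusted p = 6.75e-17; adjusted p = 0.123 with an estimated correlation). It had 15 up adjusted over the list alone, among them Srgn (2.22 ± 0.51) and the receptor gene Klrg1 (2.22 ± 0.68). The neutrophil list had 0.84 (camera adjusted p = 0.000448; adjusted p = 0.178 with an estimated correlation) and 3 up adjusted over the list alone, S100a8 among them (1.80 ± 0.46). Its median was 0.38, 0.54, 0.48 and 0.50 without wild-type PEG replicate 2, wild-type IL11 replicate 2 and Asc-/- IL11 replicates 2 and 3. Beside them the yolk sac list had a median of -3.10, and -5.81 and -7.31 without wild-type PEG replicate 1 and Asc-/- IL11 replicate 4, the latter with 25 genes down (camera adjusted p = 4.77e-22; adjusted p = 0.178 with an estimated correlation), with 0 members by either adjustment in all libraries. Over all genes 0 members of these 4 lists passed by edgeR, while 19, 16, 4 and 6 had an unadjusted p under 0.05, DESeq2 called 12, 1, 1 and 0, and limma with library quality weights 16, 4, 3 and 26. The number of genes called for the interaction was 39 without a filter on low counts and 1194 without wild type with PEG replicate 1 and Asc-/- with IL11 replicate 4. It was 30, 63, 217 and 858 without wild-type PEG replicate 1, Asc-/- PEG replicate 3, Asc-/- IL11 replicate 2 and Asc-/- IL11 replicate 4. With both wild-type PEG replicate 1 and Asc-/- IL11 replicate 4 left out, yolk sac scores of PEG and IL11 overlapped in neither genotype. They differed in opposite directions, so the 1194 calls cannot tell IL11 from tissue share.

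**Figure D4:**
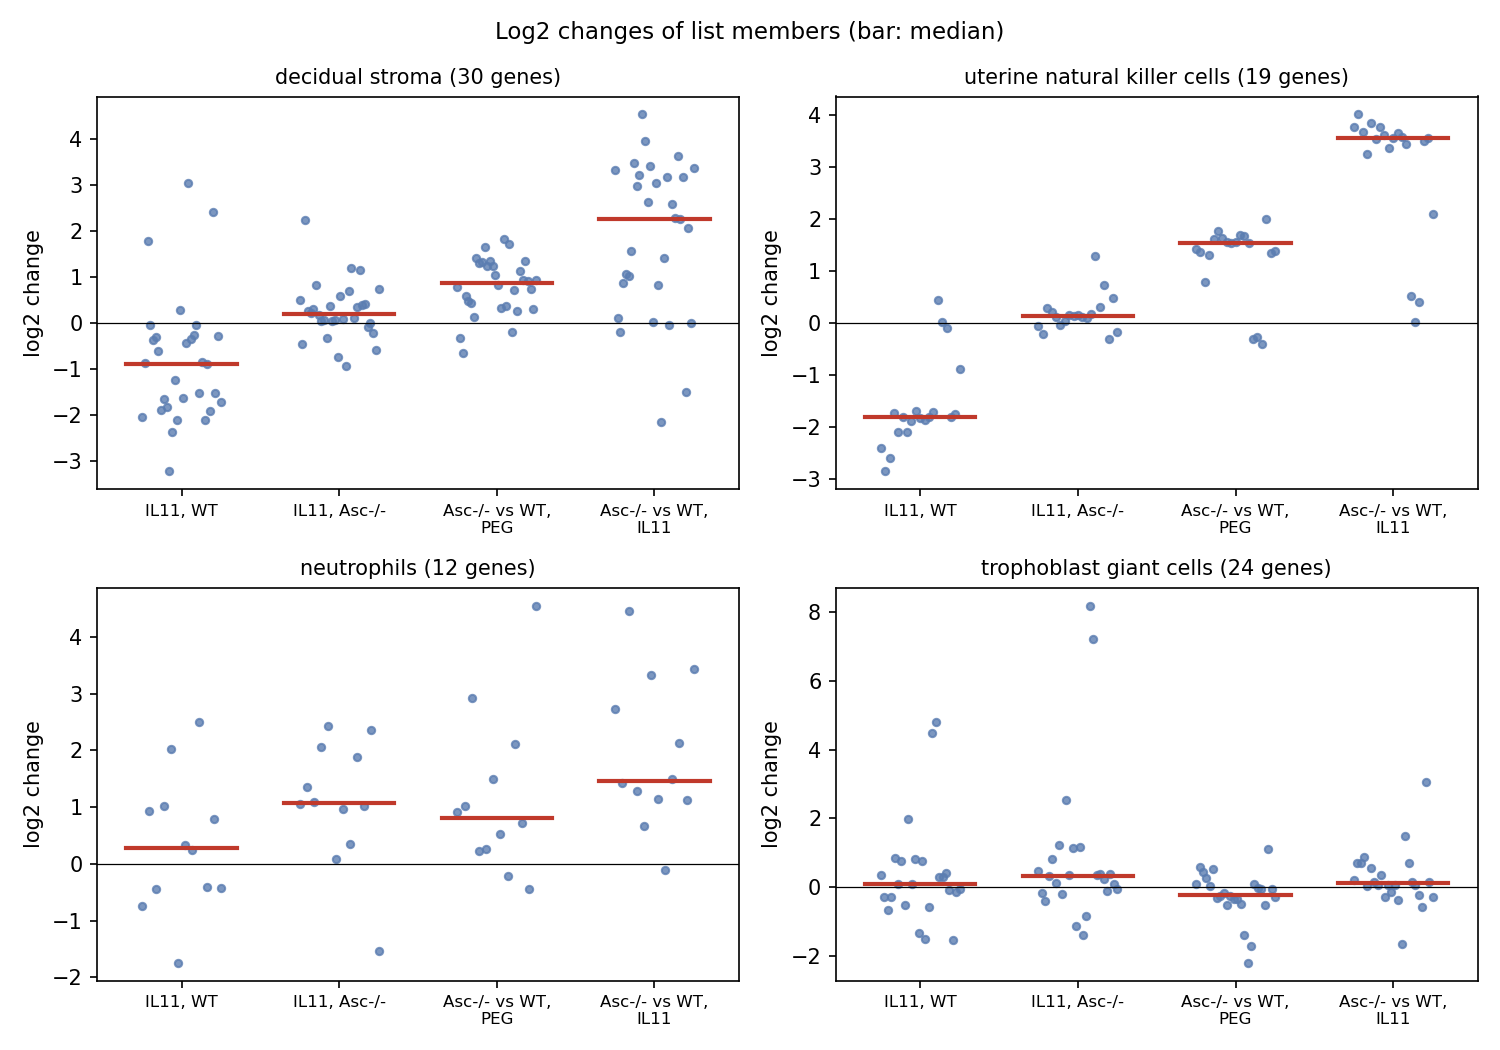
Log2 changes of the tested members of 4 gene lists in 4 comparisons, with genes as points and list medians as bars. The natural killer cell medians are -1.80 for IL11 in wild type and 3.55 for Asc-/- against wild type under IL11.

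Asc-/- and wild-type placentas under PEG, the baseline of the genotypes, differed in 10 genes by edgeR, 6 higher and 4 lower in Asc-/-, Pycard among the latter. The sample numbers in the labels run in separate ranges by genotype, and no label says whether the genotypes shared a cohort. Gdpd3, a lysophospholipase D gene on chromosome 7 at 126766414 to 126775645, was higher in Asc-/-, at 96.2 ± 20.9 against 0.506 ± 0.0928 CPM (n = 4 each, log2 7.56 ± 0.26, adjusted p = 1.83e-10). Inpp5f, a phosphoinositide phosphatase gene on the same chromosome, was higher by 0.69 ± 0.11 and Kdm8, a hydroxylase gene, lower by 0.70 on the log2 scale. Ceacam1 also lies on chromosome 7 but far from Pycard, from 25461702, and was lower, at 23.5 ± 1.15 against 40.0 ± 7.45 CPM (-0.77 ± 0.12, adjusted p = 0.0213). On chromosome 2 the Rab5 effector gene Rin2 was higher by 1.55 ± 0.12, and the predicted gene Gm34181, chosen after its values were seen, lower (-1.91 ± 0.24). Rin2 and Gm34181 also lie near each other, from 145771727 and 144337444. The tight junction gene Cldn10 was higher by 4.89 ± 0.60. The collagen gene Col6a5 had 4 counts in wild type and 1334 in Asc-/-, a ratio of 280 (95% exact counting interval 109 to 1028), which was 123 without Asc-/- PEG replicate 3 and 421 without wild-type PEG replicate 1. Serpina3h, chosen after its values were seen, had 1 and 201 counts, a ratio of 169 (29.9 to 6691), and was at least 42.2-fold higher by the floor without wild-type PEG replicate 1. Within 5 Mb of Pycard 3 of 137 tested genes other than Pycard were called, against 6 of 16317 elsewhere (two-sided Fisher's exact p = 4.57e-05, chosen after the calls were seen).

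**Figure D5:**
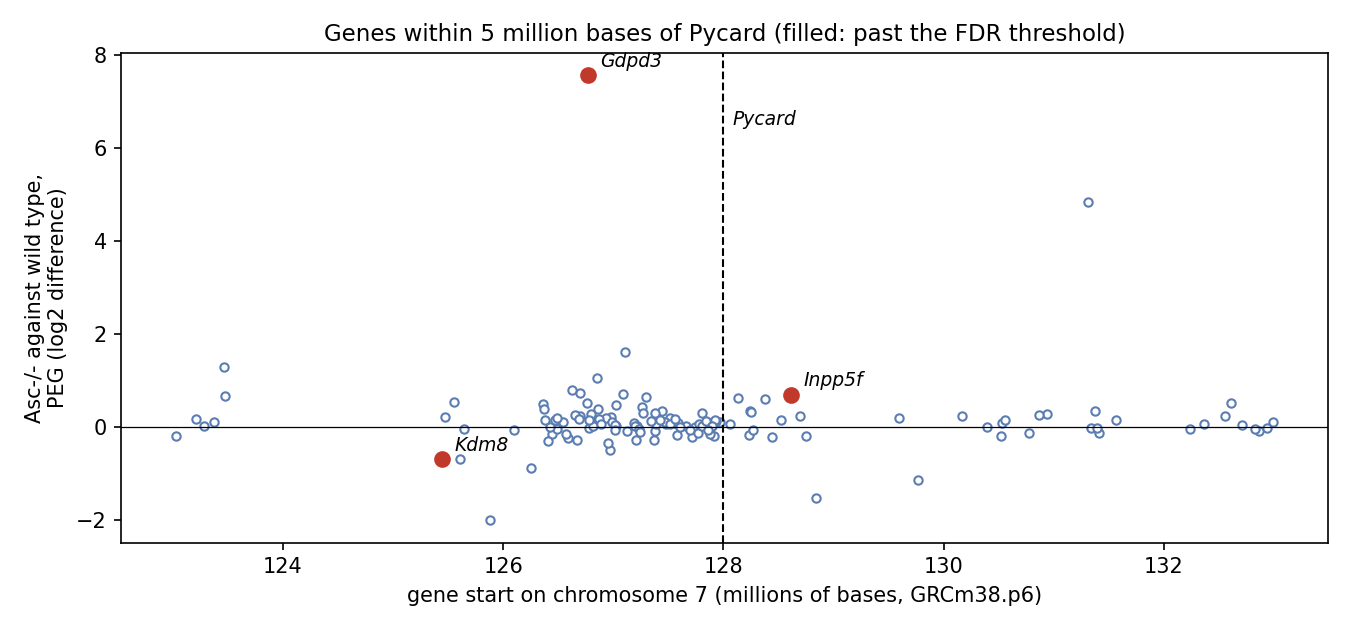
Log2 difference of Asc-/- from wild type under PEG for the tested genes within 5 Mb of Pycard on chromosome 7 (GRCm38.p6), by gene start in Mb (megabases), with filled points for Gdpd3, Inpp5f and Kdm8, which passed the FDR threshold. Pycard, whose fitted value depends on a group at 0 counts, is marked by a dashed line only.

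Lists fixed in advance also differed between genotypes under PEG by camera with its preset correlation, but none with an estimated one (smallest adjusted p = 0.333). Acute-phase genes had a median of 1.57 (camera adjusted p = 7.00e-12), with 7 of 21 up adjusted over the list alone. The members were Lcn2, the siderophore-binding lipocalin gene (4.63 ± 0.84), C3, the central complement gene (4.05 ± 0.89) and A2m, a protease inhibitor gene (2.01 ± 0.38), among others. Cell cycle genes had 13 of 40 up adjusted over the list alone (median 0.36, and 0.20 without wild-type PEG replicate 2; camera adjusted p = 4.46e-14), led by Rrm2, a ribonucleotide reductase gene (1.13 ± 0.22). Decidual stroma had 16 up and 1 down of 30 (median 0.87, camera adjusted p = 2.77e-09), with Hoxa10 at 1.41 ± 0.32. Natural killer cells had 15 up and 2 down of 19 (median 1.54, camera adjusted p = 4.49e-08), with Gzmb at 1.77 ± 0.48 (-0.055 with the maternal and yolk sac scores as covariates) and Spp1 at 2.0 ± 0.52. Gzmb is itself part of the maternal score, which did not overlap between genotypes under PEG. Spongiotrophoblast genes had 2 up and 20 down of 41 (median -0.47, camera adjusted p = 7.00e-12), with the VEGF receptor gene Flt1 at -0.62 ± 0.18 and Prl8a1 at -0.89 ± 0.24. Over all genes 0 members of these 5 lists passed by edgeR, while 12, 23, 20, 17 and 26 had an unadjusted p under 0.05, DESeq2 called 7, 4, 8, 5 and 8, and limma with library quality weights 4, 3, 1, 4 and 2. With an estimated correlation the adjusted p was 0.333 for the acute-phase list, 0.344 for the cell cycle list and 0.341 for the other 3. Beside them the yolk sac list had a median of 1.39, which was 4.05 and 0.70 without wild-type and Asc-/- PEG replicate 1. The acute-phase list shares genes with the yolk sac list, and its score followed the yolk sac score in wild type with PEG. In replicates 1 to 4 it was 3.23, 1.72, 1.42 and 2.27, beside 6.28, 2.07, 2.05 and 3.63. Whether the acute-phase difference came from yolk sac RNA was not tested. The neutrophil list had 6 up and 1 down of 12 adjusted over the list alone (median 0.82, camera adjusted p = 0.00183, and adjusted p = 0.341 with an estimated correlation), with Ltf, the lactoferrin gene, at 2.92 ± 0.56. Ltf, Lcn2 and C3, from 2 lists, were among the genes with the largest loadings at the same end of the second principal component. Which cells made these transcripts was not tested. The number of genes called was 797 with DESeq2, 278 with limma and library quality weights (120 higher and 158 lower), 40 without a filter on low counts and 23 with the PEG libraries fitted alone. It was 14 with the Y-linked score (6 higher and 8 lower), 5 with the maternal and yolk sac scores and 555 without wild type with PEG replicate 1 and Asc-/- with IL11 replicate 4. It was 19, 23 and 79 without wild-type PEG replicate 1, Asc-/- PEG replicate 2 (10 higher and 13 lower) and Asc-/- PEG replicate 4.

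Under IL11 the genotypes differed in 1537 genes by edgeR, 1250 higher and 287 lower in Asc-/-. Gdpd3 (7.66 ± 0.25), Rin2 (1.68 ± 0.12) and Kdm8 (-0.73 ± 0.11) differed as they did under PEG. Serpina3n was higher, at 104 ± 58.1 against 2.84 ± 1.58 CPM (n = 4 each, log2 5.19 ± 0.49, adjusted p = 4.21e-05). Further genes higher in Asc-/- were the AMP deaminase gene Ampd3 (3.71 ± 0.33), the sphingolipid desaturase gene Degs2 (2.79 ± 0.25) and Medag (3.10 ± 0.28). So were Lmcd1 (3.52 ± 0.32), the transporter gene Slco5a1 (3.76 ± 0.36), Cd109 (3.43 ± 0.33) and Shisa3 (4.45 ± 0.43). Genes lower in Asc-/-, apart from Pycard, included Rnf157 (-0.60 ± 0.09), the kinase gene Srms (-0.88 ± 0.13), Syt13 (-0.92 ± 0.15) and Enc1 (-0.48 ± 0.08). Also lower were Tox2 (-0.62 ± 0.11), Edrf1 (-0.31 ± 0.06), Tmem216 (-0.40 ± 0.08), the colipase gene Clps (-1.51 ± 0.29) and Pygl, the liver glycogen phosphorylase gene (-0.41 ± 0.07).

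The lists of decidual stroma, natural killer cells and neutrophils were higher in Asc-/- under IL11 with the preset and with an estimated correlation, each with an adjusted p of 0.0227 in the latter. Of 30 decidual stroma genes 21 were higher (23 up and 1 down adjusted over the list alone; median 2.26, camera adjusted p = 2.65e-30), among them Prl8a2 (3.32 ± 0.34), Hoxa10 (3.46 ± 0.36) and Pgr (3.96 ± 0.45). Of 19 natural killer cell genes 16 were higher (18 adjusted over the list alone; median 3.55, camera adjusted p = 2.86e-26), among them Srgn (3.56 ± 0.40), Gzmb (3.54 ± 0.53) and Klrg1 (3.85 ± 0.52). Of 12 neutrophil genes 6 were higher (9 adjusted over the list alone; median 1.46, camera adjusted p = 1.37e-08), among them S100a8 (2.72 ± 0.34) and Ltf (4.46 ± 0.59). These 12 were the tested genes of 21 listed, and which cells made their transcripts was not tested. Beside these lists, Y-linked transcripts were high in all 4 wild-type libraries and 1 Asc-/- library. The yolk sac list had a median of -1.68, and -6.25 with 25 genes lower without Asc-/- IL11 replicate 4. With all libraries it had 0 members past the threshold by edgeR, 6 at an unadjusted p under 0.05, 0 by DESeq2 and 25 by limma with library quality weights. Its camera adjusted p was 8.07e-09 (adjusted p = 0.475 with an estimated correlation).

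Among inflammasome genes under IL11, Casp4, the sensor of cytosolic lipopolysaccharide (2.40 ± 0.33), the pore-forming gasdermin gene Gsdmd (1.22 ± 0.25), Nek7 (0.86 ± 0.14), Txnip (0.91 ± 0.14) and the decoy receptor gene Il1r2 (2.13 ± 0.33) were higher in Asc-/-. Pycard was lower. They were 5 up and 1 down of 28 (8 and 3 adjusted over the list alone, camera adjusted p = 0.125). Preeclampsia-associated genes were higher in 12 of 32 (14 up and 1 down adjusted over the list alone; camera adjusted p = 1.50e-05; adjusted p = 0.273 with an estimated correlation). They included Adm (3.05 ± 0.35) and Inhba (2.32 ± 0.38). Acute-phase genes were higher in 8 of 21 (9 adjusted over the list alone; camera adjusted p = 0.000199; adjusted p = 0.475 with an estimated correlation). Lcn2 had 4.66 ± 0.85 and the lipopolysaccharide-binding protein gene Lbp 3.53 ± 0.42. STAT3-responsive genes were higher in 4 of 20 (8 up and 1 down adjusted over the list alone; camera adjusted p = 0.0259; adjusted p = 0.455 with an estimated correlation). Cebpd (2.80 ± 0.42) and Socs3 (1.11 ± 0.31) were among them. The gp130 pathway components Il11ra1, the IL11 receptor gene (0.83 ± 0.21), Stat3 (0.39 ± 0.08) and Clcf1 (0.99 ± 0.27) were higher. They were 3 of 13 (4 adjusted over the list alone; camera adjusted p = 0.0166; adjusted p = 0.475 with an estimated correlation). Macrophage genes were higher in 6 of 26 by either adjustment, among them Trem2 (4.51 ± 0.55) and Cd68 (1.66 ± 0.27), without a shift of the list (camera adjusted p = 0.132). Cytokine and chemokine genes were higher in 5 and lower in 1 of 25 (6 and 1 adjusted over the list alone, camera adjusted p = 0.0807), including Cxcl14 (6.04 ± 0.82) and Ccl8 (4.48 ± 0.80). H2-K1 was higher by 1.84 ± 0.29, 1 of 5 higher of 39 interferon genes (7 up and 1 down adjusted over the list alone; camera adjusted p = 0.00452; adjusted p = 0.683 with an estimated correlation). Cholesterol synthesis genes were lower in 5 of 24 (14 adjusted over the list alone; camera adjusted p = 1.80e-08; adjusted p = 0.409 with an estimated correlation). Cyp51 had -0.73 ± 0.18 and Sc5d -0.63 ± 0.15. The number of genes called was 824 with the Y-linked score as a covariate, 1 with the maternal and yolk sac scores and 1008 with the IL11 libraries fitted alone. It was 3861 with limma and library quality weights and 2957 without wild type with PEG replicate 1 and Asc-/- with IL11 replicate 4. The count was 964, 974 and 2732 without Asc-/- IL11 replicates 1, 3 and 4. The excess of higher genes was small in 3 of these: 2089 higher and 1772 lower with limma, 1539 and 1418 without the 2 libraries, and 1442 and 1290 without Asc-/- IL11 replicate 4. With the maternal and yolk sac scores as covariates the differences of Gsdmd, Nek7, Il1r2, Cd68, H2-K1, Il11ra1 and Cebpd turned negative. Maternal scores under IL11 were 2.92 to 3.45 in wild type and 4.30 to 5.61 in Asc-/-, without overlap. The covariate could hardly be told from genotype there, and Il11ra1 is itself part of the maternal score.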

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

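The camera tests of the lists and Dixon's ratio were fixed before the data were examined. The permutation of genes around Pycard was set after the calls but before its own result was seen. The other tests of the first 3 patterns were chosen after the results they bear on were seen.

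Decidual stroma and natural killer cell transcripts were lower after IL11 in wild type (medians -0.89 and -1.80), while in Asc-/- 0 members of either list fell by edgeR, DESeq2 or limma with quality weights (4 and 3 had an unadjusted p under 0.05 in either direction, and the decidual median was 0.19), and the difference between the genotypes passed camera only with its preset correlation. Dilution by yolk sac RNA is argued against, since it would lower other lists alike and the syncytiotrophoblast median lay 1.54 above the natural killer cell median. The decidual median was -0.75 with the Y-linked score as a covariate and -0.89 without it. Only 1 wild-type PEG library and all 4 wild-type IL11 libraries had high Y-linked transcripts, so this value alone cannot decide on unequal fetal sex. A smaller share of maternal tissue in the wild-type IL11 libraries stays open and may be the source: Xist, which a male fetus hardly makes, went with the maternal score over the 7 libraries with high Y-linked transcripts (Pearson r 0.993, exact permutation p = 0.000992; Spearman rho 0.964, exact permutation p = 0.00278; r 0.966 without the 2 libraries farthest from the median of Xist, the 1 relation computed). These libraries come from 4 groups, 4 of them from wild type with IL11, and no value was computed within a group. The 5 left in the last r were those 4, with Xist at 6.47 to 10.9 CPM, and wild type with PEG replicate 1, at 30.6 CPM. That r rests largely on 1 library and adds little. The permutations also exchanged libraries across groups. Whether a smaller share would come from dissection or from IL11 was not tested.

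The cathepsin, prolactin and other genes called in the same direction in both genotypes were 209. Unequal fetal sex as the whole cause is argued against in Asc-/-, where Y-linked transcripts were high in 1 library of each group. The Y-linked score as a covariate could hardly move that comparison, and 197 of the 209 passed with it. In wild type 1 PEG and all 4 IL11 libraries were high. There the median log2 change of the 209, signed by direction, was 0.80 with the covariate (quartiles 0.46 to 1.24). It was 0.82 (0.51 to 1.40) without it. Only 1 wild-type PEG library had a high score, so the wild-type value alone cannot decide. A different share of maternal or yolk sac tissue as the whole cause is argued against in Asc-/-: with both scores as covariates 163 of the 209 passed there. In wild type the median was 0.64 (0.42 to 1.16), with all 209 of the same sign. The wild-type maternal score was 4.05 to 4.10 with PEG and 2.92 to 3.45 with IL11, without overlap. The covariate could hardly be told from the treatment there, so tissue share stays open in wild type. In wild type 28 and 0 of the 209 passed with the Y-linked score and with the tissue scores. The median SE was 0.21 and 0.27 against 0.17 without, and 208 and 137 had an unadjusted p under 0.05. Why fewer passed was not tested. A part played by tissue share, reads shared between paralogs, which were not tested, and a trophoblast response to IL11 stay open, and the 209 genes had been picked by their calls without the covariates.

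Gdpd3, Inpp5f and Kdm8, called between genotypes under PEG, lie within 5 Mb of Pycard, 3 of 137 tested genes there against 6 of 16317 elsewhere. The nearness itself had a two-sided Fisher's exact p of 4.57e-05, on calls already seen to lie there, and a difference between cohorts stays open for them, since no label says whether the genotypes shared a cohort. DNA of another origin around the targeted allele, a difference between cohorts and an effect of the missing ASC cannot be told apart here. The 134 other genes of the stretch had a mean absolute z of 1.82 against 1.68 elsewhere (one-sided permutation p = 0.141), and 65.7% of them against 64.4% had the same sign under PEG and IL11. Of 13636 stretches of as many neighbouring genes 79.6% had a lower mean.

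Single libraries stood far from the other 3 of their group by Dixon's ratio. Chance puts about 1 in 20 groups past its 95% critical value. Past it were 7 of 20 groups for library measures (1 by chance), 10 of 120 for list scores (6 by chance) and 13 of 92 for gene levels (4.6 by chance). These tallies cannot be set against chance as independent tests. The Y-linked score is either high or low, so a group with 1 high library passes by construction. The yolk sac score and its list score are the same values, counted in both families, and the Pycard hit rests on 1 count. Asc-/- with IL11 replicate 2 had 31431000 counts (the others 25602000 to 26571000), and wild type with IL11 replicate 4 had 96.9% of counts in the mRNA table (97.7% to 97.8%). Y-linked scores stood apart in wild type with PEG replicate 1 (5.31), Asc-/- with PEG replicate 3 (5.10) and Asc-/- with IL11 replicate 2 (5.13). Asc-/- with PEG replicate 3 also had a maternal score of 5.48 (4.78 to 4.84), with 5.51 for decidual stroma (4.92 to 4.97), 5.36 for natural killer cells (4.56 to 4.65), 37.6 CPM for Pgr (17.9 to 18.8) and 298 CPM for Gzmc (120 to 136). The yolk sac score of Asc-/- with IL11 replicate 4 was 7.16 (1.95 to 2.47), with 12257 CPM for Afp (18.8 to 66.1) and 5.52 for cholesterol synthesis (4.84 to 4.92). Wild type with PEG replicate 1 had 5950 CPM for Afp (19.7 to 392.3). Wild type with IL11 replicate 2 had a STAT3-responsive score of 3.81 (4.2 to 4.25), 931 CPM for Ctsm (643 to 677), 1912 CPM for Cts3 (938 to 1080), 34.6 CPM for Tfpi2 (19.3 to 20.1) and 3.92 CPM for Shisa3 (1.51 to 1.89). Replicate 3 of that group had a decidual stroma score of 3.41 (3.77 to 3.8). Asc-/- with IL11 replicate 1 had an endothelium score of 5.30 (5.07 to 5.09), 733 CPM for Ctsm (640 to 654) and 1173 CPM for Cts3 (874 to 893), and replicate 2 had 6.47 for oxidative phosphorylation (6.38 to 6.39) and 0.0314 CPM for Pycard, which had 0 counts in the others. Wild type with PEG replicate 2 had a cell cycle score of 4.37 (4.89 to 4.97), a Pycard neighbourhood score of 4.08 (3.94 to 3.95) and 4449 CPM for Cts3 (3102 to 3304), and replicate 4 had 14.9 CPM for Fgf2 (9.26 to 9.91).

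The IL11 responses of the genotypes differed for 17 of 30 lists by camera with its preset correlation and for 0 with an estimated one (smallest adjusted p = 0.123). The camera adjusted p was 4.77e-22 for visceral endoderm and yolk sac, 1.82e-17 for decidual stroma, 6.75e-17 for natural killer cells, 3.59e-13 for cholesterol synthesis, 6.18e-11 for cell cycle and 2.33e-09 for the unfolded protein response. It was 8.40e-06 for spongiotrophoblast, 0.000184 for preeclampsia-associated genes, 0.000448 for neutrophils, 0.000497 for the interferon response, 0.000850 for endothelium and 0.00149 for oxidative phosphorylation. For gp130 pathway components it was 0.00181, for syncytiotrophoblast and giant cells 0.00444 each, for platelets 0.00668 and for hypoxia and glycolysis 0.0280.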

How the results depend on the processing

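The mRNA table, the recovered reads, the covariates and the 14 libraries (without wild-type PEG replicate 1 and Asc-/- IL11 replicate 4) were chosen after seeing the data; so was the permutation of residuals, while the splits of the libraries and the other alternatives were planned. RLE factors, a mean CPM of at least 1, the mRNA table and the recovered reads left the 5 gene counts and the shared genes within 1.5 times their values, and TMM and RLE left the median change of all genes within 0.024 of 0. In wild type (1154 genes) DESeq2 gave 2121, limma with quality weights 4234, the Y-linked score 70, the maternal and yolk sac scores 1 and the 14 libraries 2343; leaving out 1 library gave 344 to 2269 (1773, 552 and 718 without PEG replicates 1, 3 and 4; 467, 2269, 344 and 574 without IL11 replicates 1 to 4). In Asc-/- (476) DESeq2 gave 851, limma 1167 and the 14 libraries 1201; leaving out 1 gave 184 to 821 (266, 283, 293 and 260 without PEG replicates 1 to 4; 306, 184 and 821 without IL11 replicates 2, 3 and 4). For the interaction (0) no filter gave 39, DESeq2 210, limma 1410 and the 14 libraries 1194; leaving out 1 gave 0 to 858 (30, 63, 217 and 858 without wild-type PEG replicate 1, Asc-/- PEG replicate 3 and Asc-/- IL11 replicates 2 and 4). Between genotypes under PEG (10) no filter gave 40, DESeq2 797, only these groups 23, limma 278, the Y-linked score 14 (6 higher, 8 lower), the tissue scores 5 and the 14 libraries 555; leaving out 1 gave 7 to 79 (19, 23 and 79 without wild-type PEG replicate 1 and Asc-/- PEG replicates 2 and 4). Under IL11 (1537) only these groups gave 1008, limma 3861, the Y-linked score 824, the tissue scores 1 and the 14 libraries 2957; leaving out 1 gave 964 to 2732 (964, 974 and 2732 without Asc-/- IL11 replicates 1, 3 and 4). Shared genes (209) were 407 with DESeq2, 122 with each genotype alone, 558 with limma, 29 with the Y-linked score and 0 with the tissue scores; leaving out 1 gave 93 to 341 (115, 102, 341 and 93 without wild-type PEG replicate 3 and IL11 replicates 1 to 3; 129 and 113 without Asc-/- PEG replicate 4 and IL11 replicate 3). In opposite directions 382 genes passed with the 14 libraries. In these 14 the yolk sac scores of PEG and IL11 overlapped in neither genotype and differed in opposite directions. Their gene counts and r cannot tell IL11 from tissue share. The r across all genes (0.116) was -0.528 with the 14 libraries and -0.347 to 0.321 with 1 library left out (0.00373 and 0.0506 without wild-type PEG replicate 1 and IL11 replicate 3; 0.321, 0.0357 and 0.050 without Asc-/- PEG replicates 1 to 3; 0.271, 0.217 and -0.347 without Asc-/- IL11 replicates 1, 3 and 4). The replicate number as a block gave 666, 218 and 0 genes for IL11 in wild type, in Asc-/- and the interaction, 162 and 1909 between genotypes under PEG and IL11, and 101 shared; as 7 of 16 same-numbered pairs had an r over 0.1 (-0.32 to 0.47), the numbers were not taken to pair the samples. In the order of the comparisons 17, 11, 17, 13 and 14 of 30 lists passed camera, 0, 1, 0, 0 and 3 with an estimated correlation and 3, 3, 0, 3 and 12 with fry. Over the alternatives, 206 calls of named genes gave 4103 values, of which 3451 kept the direction and stayed past the threshold, 639 kept the direction only and 13 turned. With both tissue scores as covariates the sign turned for H2-K1 (0.045), Adm (0.0010) and Icam1 (0.026) after IL11 in wild type, Gzmb (-0.055) under PEG, and Gsdmd (-0.33), Nek7 (-0.21), Il1r2 (-0.67), Cd68 (-0.70), H2-K1 (-0.89), Il11ra1 (-0.77), Cebpd (-0.36), Vegfa (-0.29), Dcn (-0.28) and Igf2 (0.082) under IL11, with none past the threshold. In all these cases the cause was not tested. Maternal scores did not overlap between the groups of these comparisons, so the covariate could hardly be told from IL11 or genotype. Il11ra1, Dcn and Gzmb are also part of the maternal score. Over 35 splits of the 8 libraries the highest other count was 353 for IL11 in wild type and 288 in Asc-/-. It was 0 between genotypes under PEG and 33 under IL11. For these 4 counts 1 split, the real one, reached the count, the smallest share that 35 splits can give. Chance was thus made less likely but not excluded, as litters are not labelled. Between genotypes the splits say little, since every other split mixes Asc-/- with wild-type libraries and Pycard differs by design. For the interaction (1919 genes at an unadjusted p under 0.05) regrouping treatment within genotype cannot decide, since unequal exchanges turn the shared response into a difference: 10 of 100 splits, the real one included, reached the count, the highest with 4035 genes and all 4 wild-type PEG libraries exchanged, and 0 of the 26 with 2 of 4 exchanged in both genotypes (highest 1383). With the main effects kept and the residuals permuted, 6 of 100 arrangements reached limma's 2170, with 4111 the highest other, so chance cannot be excluded. At 22.6 to 33.0 M counts, Pycard and other genes with few counts are limited to floors and counting intervals.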

Other observations

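Further lists fixed before the data were examined had few members past the threshold after IL11 in wild type. Of 25 cytokine and chemokine genes Nos2 rose (0.53 ± 0.15, SE), and the chemokine genes Cxcl14 (-4.14 ± 0.81) and Cxcl12 (-0.55 ± 0.12) and the adhesion gene Icam1 (-0.84 ± 0.22, but 0.026 with the maternal and yolk sac scores as covariates) fell (3 up and 6 down adjusted over the list alone; camera adjusted p = 0.0394; adjusted p = 0.547 with an estimated correlation). Of 26 macrophage genes Cd68 (-1.27 ± 0.27) and Trem2 (-2.37 ± 0.53) fell by either adjustment (camera adjusted p = 0.656). Of 13 genes of T cells, B cells and dendritic cells Flt3 (-0.90 ± 0.16) and H2-Aa (-1.69 ± 0.47) fell (1 up and 5 down adjusted over the list alone; camera adjusted p = 0.0212; adjusted p = 0.433 with an estimated correlation). Of 28 erythroid genes the membrane skeleton gene Add2 fell (-0.76 ± 0.22), and 0 when adjusted over the list alone (median -0.36, camera adjusted p = 0.00298; adjusted p = 0.547 with an estimated correlation). Of 14 platelet genes the collagen receptor gene Gp6 fell (-1.02 ± 0.29; 1 up and 2 down adjusted over the list alone, camera adjusted p = 0.0533). Among 15 pericyte and smooth muscle genes Des and Pdgfrb (-0.42 ± 0.09) fell (1 up and 2 down adjusted over the list alone, camera adjusted p = 0.349). Hypoxia and glycolysis genes fell in 3 of 31, Adm, Egln3 (-1.46 ± 0.36) and Ndrg1 (-0.42 ± 0.11), with 2 up and 5 down adjusted over the list alone (camera adjusted p = 0.645). Immediate-early and heat-shock genes had the chaperone genes Hspa8 (0.33 ± 0.09) and Hsph1 (0.49 ± 0.13) up and Atf3 (-0.37 ± 0.11) down of 29, by either adjustment (camera adjusted p = 0.799). Of 28 imprinted genes H19 rose (0.34 ± 0.09), and Tfpi2 and the proteoglycan gene Dcn (-1.71 ± 0.43) fell by either adjustment (camera adjusted p = 0.685). The list of the Pycard neighbourhood had 0 of 24 genes past the threshold by edgeR with either adjustment in both IL11 comparisons (camera adjusted p = 0.394 and 0.410).

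In Asc-/- the platelet receptor gene Clec1b rose after IL11 (2.06 ± 0.28), 1 of 14 by either adjustment (camera adjusted p = 0.446), and the prostaglandin synthase gene Ptgs2 fell (-0.86 ± 0.20). Pericyte genes had Rgs5 up (0.88 ± 0.17) and Pdgfrb down (-0.43 ± 0.09), with 1 up and 7 down adjusted over the list alone (median -0.43, camera adjusted p = 0.00192; adjusted p = 0.479 with an estimated correlation). Add2 fell (-0.90 ± 0.21), the 1 of 28 erythroid genes by either adjustment (median -0.50, camera adjusted p = 0.000342; adjusted p = 0.798 with an estimated correlation). Under IL11 immediate-early and heat-shock genes were higher in Asc-/- than in wild type in 6 and lower in 2 of 29 (12 and 5 adjusted over the list alone; median 0.41, camera adjusted p = 0.0166; adjusted p = 0.601 with an estimated correlation). Among them were Fos (1.54 ± 0.34) and Dusp1 (0.69 ± 0.14), and the chaperone gene Hspa1b was lower (-1.22 ± 0.34). Hypoxia and glycolysis genes were higher in 5 of 31 by either adjustment, with Egln3 at 2.43 ± 0.36 and Vegfa at 0.67 ± 0.14 (camera adjusted p = 0.00836; adjusted p = 0.601 with an estimated correlation). The matrix genes Fbln2 (3.52 ± 0.40) and Dcn (3.36 ± 0.46) were 2 of 5 higher matrix genes of 39 (12 up and 2 down adjusted over the list alone, camera adjusted p = 0.399). Of imprinted genes Tfpi2 (3.51 ± 0.40) and Dcn were higher and Igf2 lower (-0.27 ± 0.08; camera adjusted p = 0.412). With the maternal and yolk sac scores as covariates the differences of Vegfa, Dcn and Igf2 under IL11 turned sign (-0.29, -0.28 and 0.082). Dcn is itself part of the maternal score, which did not overlap between genotypes under IL11. Syncytiotrophoblast genes were higher in 5 of 26 (9 adjusted over the list alone; camera adjusted p = 0.00800; adjusted p = 0.475 with an estimated correlation) and endothelial genes in 3 of 20 by either adjustment (camera adjusted p = 0.000987; adjusted p = 0.475 with an estimated correlation). Under PEG the matrix list had 3 up and 1 down adjusted over the list alone (median 0.53, camera adjusted p = 0.00183; adjusted p = 0.476 with an estimated correlation) and the pericyte list 7 up and 1 down (median 0.52, camera adjusted p = 0.0126; adjusted p = 0.476 with an estimated correlation). Further lists passed camera under PEG with 0 members by edgeR with either adjustment: the unfolded protein response (median -0.21, camera adjusted p = 1.35e-08; adjusted p = 0.388 with an estimated correlation), oxidative phosphorylation (0.11, camera adjusted p = 0.00129; adjusted p = 0.728 with an estimated correlation), macrophages (0.39, camera adjusted p = 0.0115; adjusted p = 0.728 with an estimated correlation) and giant cells (-0.22, camera adjusted p = 0.0309; adjusted p = 0.695 with an estimated correlation). In them 14, 9, 5 and 6 members had an unadjusted p under 0.05, DESeq2 called 3, 0, 1 and 3, and limma with library quality weights 1, 0, 0 and 0. After IL11 in Asc-/- oxidative phosphorylation had a median of 0.07 with 0 members by edgeR, DESeq2 or limma and 2 at an unadjusted p under 0.05 (camera adjusted p = 0.0399; adjusted p = 0.798 with an estimated correlation).

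The signs of the median, the mean and the camera test were not all alike for 4 of 30 lists after IL11 in wild type, 6 in Asc-/-, 3 for the difference between them, and 4 and 8 for the genotypes under PEG and IL11. Of these lists 0 passed camera.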
